A study of Mus musculus with 12 samples.

How the data were processed

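The data were RNA sequencing measurements of gene expression in 12 samples of mouse blood cancer cells and T cells, in 6 groups of 2 libraries each. All samples were labelled as knockout for Tet2, an enzyme that oxidises methylated cytosine in DNA and is often lost in human blood cancers. Normal CD4+ T cells and CD4+ lymphoma cells had been taken from spleen and lymph node with a CD4+ isolation kit. CMML cells (chronic myelomonocytic leukaemia, a cancer of the monocyte and granulocyte lineages) had been enriched with antibodies against Mac1 and Gr1, surface proteins of myeloid cells. For the antibiotic experiment, lymphoma or CMML cells had been transferred into recipient mice that carry the CD45.1 marker, whose Tet2 genotype the labels do not give. The treated recipients had received a cocktail of antibiotics (ABX) for 10 days and were analysed after a further 20 days without it, and the others served as vehicle controls. RNA had been extracted with a column kit, and libraries followed the usual Illumina protocol.

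The authors deposited 2 tables of genes by libraries, of 24061 and 24062 genes named by symbol. Per the labels, the authors used Bowtie2 and DESeq2, with no versions given, and both mm10 and hg19 were named as genome builds without a role. The read counter and the gene annotation were not given in the sources used here. The deposited signal in each column is a gene read count divided by 1 size factor per library, called a normalized read count below. Every value in each column was a whole multiple of the smallest value in that column, within a tolerance of 0.001, so whole reads were recovered by dividing by that step. The primary table holds normal CD4+ T cells, lymphoma and CMML vehicle. It also holds 2 columns of libraries from another study, which were left out. The antibiotic table holds lymphoma and CMML with vehicle and with antibiotics. The CMML vehicle libraries have the same reads in both tables. Size factors recomputed by the median of ratios were identical to the deposited ones, up to 1 constant, when the 4 lymphoma and the 4 CMML libraries of the antibiotic table were treated apart, and differed by a ratio of 0.68955 to 1.46095 when all 8 were treated together. The lymphoma and CMML parts of that table are therefore not on 1 scale.

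Depth was taken as the sum of recovered reads per library. The most abundant gene took at most 2.14% of the reads of a library. The spread between the 2 libraries of a group was compared with counting noise over genes with at least 20 reads in the pair. The chi-square per degree of freedom was 1.5 for CMML vehicle, 1.51 for CMML with antibiotics, 1.91 for lymphoma with antibiotics and 2.37 for lymphoma with vehicle, against 18.1 for normal CD4+ T cells and 28.5 for lymphoma of the primary table. The labels do not say whether the replicates of a group came from separate animals. The p-values below measure differences against the spread between these libraries only. The reads carry no molecular identifiers, so counting intervals and floors cover counting error only.

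Differences between groups were tested with limma 3.58.1 in R 4.3.3, with a trend of the variance on expression, on log2 of the normalized read count plus 1. Genes with a value of at least 10 in at least 2 libraries of the table were tested, all groups of a table shared 1 estimate of the spread, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The comparisons were lymphoma against normal CD4+ T cells, antibiotics against vehicle in lymphoma and in CMML, the difference between those antibiotic effects (an interaction term), and CMML vehicle against lymphoma vehicle as a check of cell identity. The replicate numbers did not pair the libraries: log2 changes of libraries with the same number correlated at -0.02, 0.01 and 0.02 in the first 3 comparisons.

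Before the data were examined, 46 gene lists (pathways, cell states and markers of the cell types a spleen or lymph node sample could hold), the tests, the rule for naming genes and most alternatives were fixed. Of the 836 genes in the lists, 811 were found in the tables by symbol or older symbol. Lists with at least 5 tested members were tested with camera of limma, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. The Th17 list, the mitochondrially encoded genes and the nuclear retained RNAs had too few measured members. Besides camera, fry was run, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes. For each list the number of members past the threshold is given, out of the members tested, over all genes tested and adjusted over the list alone. The named genes were the 10 per direction with the largest change among those past the threshold, with no overlap between groups and a mean of at least 50 in 1 group (5 per direction for the last 2 comparisons), up to 4 members per list with the smallest p, and Tet2. Predicted genes without a proper name and antigen receptor segments were left out of that rule. Other genes that are named were chosen after their values were seen, and the text says so. Some genes that met the rule are not reported here. A planned description of antigen receptor and immunoglobulin segments was not analysed here, since the tables hold too few of them. The 200 genes per direction that most separated lymphoma from normal CD4+ T cells were also tested with camera in the antibiotic comparison of lymphoma.

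Errors given after ± are standard deviations of 2 libraries for normalized read counts and standard errors from limma for log2 fold changes. Where all libraries of a group had 0 reads, the fold is a lower bound against 3 reads over the group. With 1 to 3 reads, the ratio is given with its exact counting interval. Positions are from the GRCm38 annotation of RefSeq, the assembly also called mm10.

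The procedure was tested on simulated reads drawn from the means, depths and spread of the real libraries, with 50 genes changed at each of 4 fold sizes. At 4-fold and 2-fold, limma recovered 94% and 80% of changed genes in the comparison of antibiotics in lymphoma (13815 genes), 88% and 76% in CMML (13763 genes), 86% and 66% for the interaction (13739 genes) and 98% and 76% for CMML against lymphoma (13686 genes). Of the calls made there, 46 of 191, 9 of 141, 6 of 118 and 19 of 146 were wrong, so the stated false discovery rate was exceeded, most for antibiotics in lymphoma. For lymphoma against normal CD4+ T cells (13431 genes), recovery was 12% at 4-fold and 2% at 2-fold with 1 wrong call of 8, so a list of few changes would mostly be missed there. At 1.5-fold, recovery was 64% for antibiotics in lymphoma, 64% in CMML, 40% for the interaction, 60% for CMML against lymphoma and 0% for lymphoma against normal cells. A planted list of 20 genes was found by camera in each of the 4 comparisons with lists, with 0 other lists past the threshold. With an estimated correlation it was missed for lymphoma against normal CD4+ T cells (adjusted p = 0.418) and found in the other 3. With fry it was found in all 4, but 1 to 4 lists that had not been planted also passed. The simulated genes were drawn independently of each other. Real lists had estimated correlations such as 0.646, for ribosomal proteins in lymphoma against normal CD4+ T cells. The 0 other lists past the threshold therefore say little about false lists with the preset correlation.

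Alternatives were pseudocounts of 0.5 and 5, no filter on low values, a mean of at least 50, TMM scaling, quantile normalization, a fit of only the groups compared, the replicate number as a block, each replicate left out in turn, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, a minimum log2 change of 1, and for lists an estimated correlation and fry. Where 1 replicate is left out, the lone library of its group is assumed to vary like the other groups.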

Results

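RNA sequencing measured gene expression in 12 samples of mouse cells labelled as Tet2 knockout, in 6 groups of 2 libraries: normal CD4+ T cells, CD4+ lymphoma cells, transferred lymphoma with vehicle and with antibiotics, and CMML with vehicle and with antibiotics. The reads assigned to genes were 27137994 and 23518660 for normal CD4+ T cells and 30546079 and 2916648 for lymphoma. They were 4364587 and 8722316 for lymphoma with vehicle, and 13651031 and 12689701 for lymphoma with antibiotics. CMML with vehicle had 16777694 and 20446004 reads, and CMML with antibiotics had 19243153 and 18447658. Between 13314 and 16107 genes had a read in each library. Values are mean normalized read counts ± SD of 2 libraries unless named otherwise.

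Lymphoma against normal CD4+ T cells asked which genes are expressed differently in the lymphoma than in CD4+ T cells isolated in the same way. The lymphoma samples had far more transcripts of dividing cells: Cdk1, the kinase that drives mitosis, stood at 2270 ± 241 against 358 ± 29.4, and Kif20a, a mitotic motor protein, at 2050 ± 149 against 293 ± 17.8. Cd4 itself was alike in both groups, at 7580 ± 1350 in lymphoma and 7730 ± 694 in normal cells. The samples of normal CD4+ T cells held many transcripts of other cells, such as the B cell gene Cd79a at 10700 ± 600 against 2760 ± 508 and the macrophage gene Vcam1 at 22200 ± 4110 against 2600 ± 704. Of the genes largely confined to the lymphoma samples, Dlk1, a growth regulator expressed mainly before birth, stood at 9150 ± 3750, against 1 read in the normal cells. Cd4, Cd3e, Cd79a and Vcam1 were named here as markers of cell types after their values were seen.

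Of 13672 genes tested, 3612 were higher and 3694 lower in lymphoma, 2505 and 2773 of them by at least 2-fold. These counts depended on the libraries kept: both were smaller without either normal CD4+ library and larger without either lymphoma library. Leaving out 1 library also takes its pair out of the estimate of the spread, so these shifts do not single out a library. The lymphoma libraries differed from each other in depth and by far more than counting noise. For Cd4 the change was -0.04 ± 0.16 in log2 (adjusted p = 0.865), and it turned positive, at 0.15 without lymphoma library 1 and 0.05 without normal CD4+ library 1. For the T cell receptor gene Cd3e it was 0.47 ± 0.18 (adjusted p = 0.0679). This passed the threshold without lymphoma library 1 (adjusted p = 0.00343) and with edgeR (adjusted p = 0.0408).

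**Figure D1:**
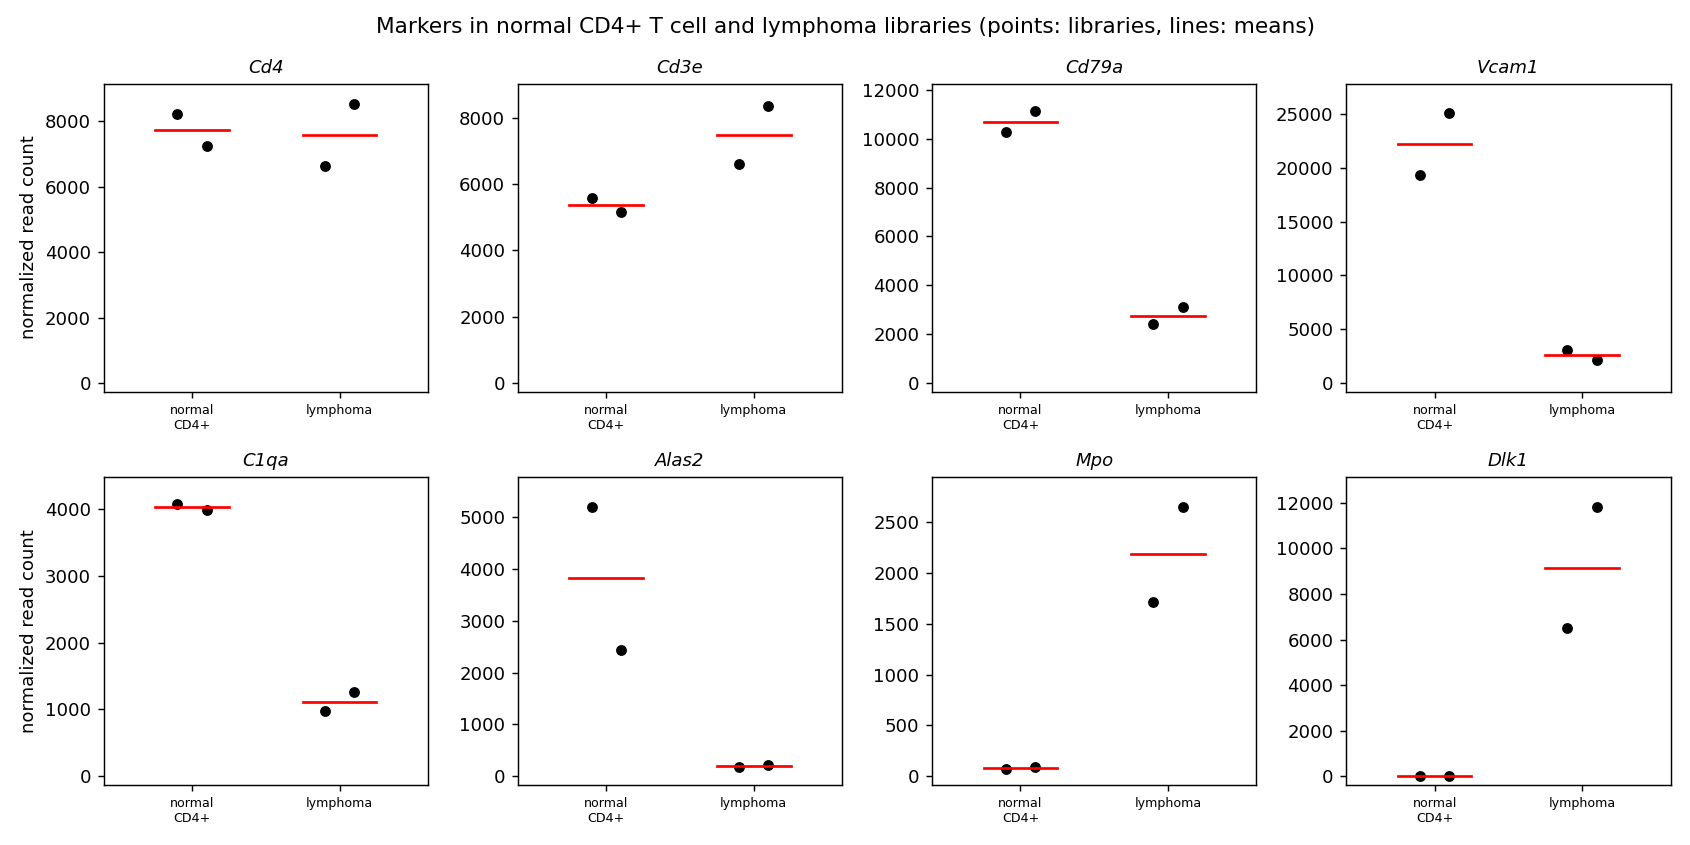
Normalized read counts (linear axes) of the cell-type genes Cd4, Cd3e, Cd79a, Vcam1, C1qa, Alas2 and Mpo and of Dlk1 in the 2 normal CD4+ T cell and 2 lymphoma libraries, with group means. Cd4 was alike in both groups, while Cd79a, Vcam1, C1qa and Alas2 were lower and Mpo and Dlk1 higher in lymphoma.

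The largest rises in lymphoma were those of Dlk1, Xist, Adamtsl3, Tnni1, Akap6, Sox13, Moxd1, Adamts20, Nes and Slc1a6. Dlk1 (chromosome 12, 109452485 to 109463336, protein coding) was higher by a ratio of 19800, with a counting interval of 3550 to 782000. Adamtsl3, a secreted matrix protein, was at least 1030-fold higher, and the glutamate transporter gene Slc1a6 at least 314-fold higher, with 0 reads in the normal cells. The cardiac and muscle genes Tnni1 and Akap6 rose from 1.36 ± 0.872 each to 1670 ± 738 and 1540 ± 184. Nes, which encodes the intermediate filament nestin, was higher by a ratio of 847, with an interval of 234 to 7000. Xist, the RNA that silences 1 X chromosome in female cells, rose from 4.63 ± 1.88 to 10800 ± 6000 (log2 change 10.82 ± 0.43, adjusted p = 0.000447). The Y-linked gene Ddx3y, chosen after its values were seen, stood at 3321 and 3611 in the normal libraries and 934.9 and 277.3 in the lymphoma libraries, so these groups also differed in sex-linked transcripts.

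**Figure D2:**
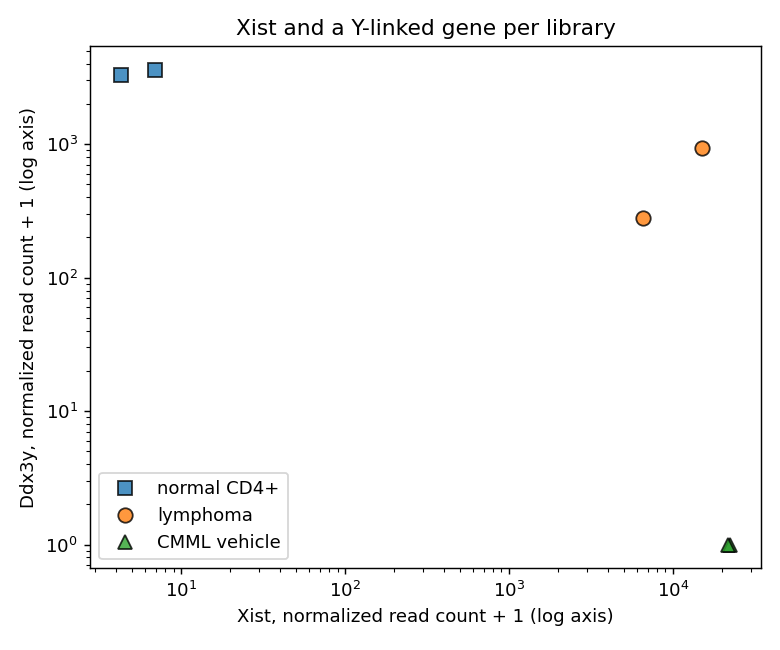
Normalized read count plus 1 of Xist (x axis) and of the Y-linked gene Ddx3y (y axis), on log axes, in each library of normal CD4+ T cells, lymphoma and CMML vehicle. Only the lymphoma libraries, at 15020 and 6538 for Xist, hold many reads of both genes.

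The largest falls were those of Cr2, Sostdc1, Kcnj2, Ermap, Tdrp, Cd8a, Tppp, Slc38a5, Tlr11 and Atp1b2. Cr2 (chromosome 1, 195136811 to 195176880, protein coding), a complement receptor of B cells and follicular dendritic cells, fell from 6670 ± 114 to 31 ± 33.5 (log2 change -8.28 ± 0.86, adjusted p = 0.00137). Sostdc1, a secreted BMP inhibitor made by some follicular T cells, was at least 138-fold lower. Ermap, Tdrp and Cd8a lost their calls without normal CD4+ library 1 (adjusted p = 0.0588, 0.0649 and 0.0866) or 2 (0.0558, 0.0692 and 0.0928). Tet2 fell from 1085 and 1233 in the normal libraries to 767.6 and 394 in the lymphoma libraries (log2 change -1.07 ± 0.31, adjusted p = 0.0331). All samples were labelled as Tet2 knockout, and counts per gene do not show which part of Tet2 the reads came from.

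Of the 43 gene lists tested, 19 passed the threshold in camera for lymphoma against normal cells, and 0 of them with an estimated correlation, where adjusted p ran from 0.288 to 0.466. The counts of changed genes below are over all genes tested and, where they differ, also adjusted over the list alone. All 34 genes of the G2/M list rose, with a median log2 change of 2.33 (adjusted p = 1.44e-15), led by Kif20a, Kif2c and Cdk1. Of the 34 G1/S genes, 32 rose, with a median of 2.12 (adjusted p = 8.5e-13), among them Uhrf1 at 8430 ± 955 against 918 ± 84.6. The methyltransferase gene Dnmt1 rose from 3200 ± 67.8 to 9980 ± 2240, but its list of DNA methylation and TET enzymes did not pass, with 6 of 14 higher and 3 lower (median 0.24, adjusted p = 0.395). In the MYC and ribosome biogenesis list 27 of 30 genes rose (29 adjusted over the list alone), with a median of 1.17 (adjusted p = 4.97e-09). Cytosolic ribosomal proteins had a median of 1.12 with 41 of 46 higher (44 adjusted over the list alone, adjusted p = 9.85e-10). Oxidative phosphorylation had a median of 1.12 with 43 of 49 higher (46 adjusted over the list alone, adjusted p = 2.72e-11). Glycolysis and hypoxia genes had a median of 1.53 with 17 of 25 higher (18 adjusted over the list alone, adjusted p = 1.97e-06), Gapdh rising from 5430 ± 422 to 46200 ± 8080 and Egln3 from 77.6 ± 34.9 to 3310 ± 75.2.

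The Th2 list rose in lymphoma, with 7 of 8 genes higher, 1 lower and a median of 3.12 (adjusted p = 0.00285). Gata3, the regulator of Th2 cells, rose from 816 ± 1.63 to 3650 ± 203, and the IL-25 receptor gene Il17rb from 69.1 ± 12.3 to 1410 ± 174. Neutrophil genes rose too, 18 of 21 with 1 lower and a median of 2.26 (adjusted p = 2.76e-07), as did primary granule genes, 7 of 8 with a median of 4.09 (adjusted p = 9.83e-05). Mpo, the granule peroxidase of immature neutrophils, rose from 83 ± 17.6 to 2180 ± 659. The counts do not show whether the neutrophil and granule transcripts came from the lymphoma cells or from other cells in the samples.

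Interferon genes fell in lymphoma. In the type I interferon list 27 of 32 genes were lower, with a median of -1.8 (adjusted p = 7.22e-08), and in the interferon gamma list 19 of 26 were lower and 2 higher, with a median of -1.79 (adjusted p = 9.72e-05). In the Toll-like receptor list 18 of 24 genes fell (19 adjusted over the list alone), with a median of -1.41 (adjusted p = 2.79e-05), Tlr7 from 2640 ± 169 to 253 ± 99.9. The counts do not show which cells the interferon and Toll-like receptor transcripts came from. Several lists of other cells fell as well, unlike the neutrophil and primary granule lists, which rose. The medians were -2.11 for B cell genes, with 15 of 16 lower (adjusted p = 8.42e-08), and -1.55 for plasma cell genes, with 6 of 7 lower (7 adjusted over the list alone, adjusted p = 0.00345). They were -2.87 for macrophage genes, with 15 of 17 lower (adjusted p = 8.62e-08), and -3.89 for erythroid genes, with 16 of 17 lower (adjusted p = 3.13e-06). For CD8 and NK cell genes 8 of 11 were lower and 1 higher (10 and 1 adjusted over the list alone), with a median of -3.9 (adjusted p = 0.00481). The myeloid identity list had a median of -0.84, with 11 of 20 lower and 2 higher (adjusted p = 0.00277). The monocyte list had a median of -0.61, with 9 of 19 lower and 3 higher (adjusted p = 0.0381), and lost its call without lymphoma library 1 (adjusted p = 0.188).

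Lists of T cell states held genes that moved in either direction. The normal samples held more transcripts of several other cell types, such as Cd79a at 10700 ± 600 against 2760 ± 508. The lymphoma samples held more neutrophil transcripts, such as Mpo at 2180 ± 659 against 83 ± 17.6. A fall or a rise below therefore need not be a change within T cells. The follicular helper list did not pass, with 6 of 18 higher and 8 lower (7 and 9 adjusted over the list alone, median -0.9, adjusted p = 0.472): its regulator Bcl6 fell from 1520 ± 115 to 370 ± 27.6 and Cxcr5 from 3410 ± 108 to 733 ± 129, while the costimulator Icos rose from 1660 ± 177 to 13400 ± 4140. In the Th1 and cytotoxic list, 10 of 16 were lower and 2 higher (median -1.36, adjusted p = 0.0647): Tbx21 fell from 316 ± 39.2 to 64.4 ± 1.85 and the granzyme gene Gzma rose from 235 ± 11.8 to 8200 ± 1910. The inhibitory receptor list did not pass either, with 6 of 10 higher and 3 lower (median 1.34, adjusted p = 0.292), though Ctla4 rose from 798 ± 15.9 to 5690 ± 2060 and Lag3 from 780 ± 49 to 3860 ± 1360.

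The comparison of antibiotics with vehicle in transferred lymphoma asked what a 10-day cocktail changed in the lymphoma samples 20 days after its end. The samples from treated mice held many more transcripts of red cell precursors, and Slc4a1, the anion exchanger of red cells, rose from 62.1 ± 17.7 to 2280 ± 39.9. Macrophage genes rose with them, Vcam1 from 151 ± 5.52 to 951 ± 79.3 and the haem-degrading enzyme gene Hmox1 from 194 ± 12.7 to 633 ± 19.2. Genes of MHC class I fell: the heavy chain gene H2-K1 went from 15300 ± 198 to 8390 ± 154 and its partner B2m from 15100 ± 359 to 9950 ± 83.3. Grb10, an adaptor that restrains insulin signalling, fell from 2170 ± 180 to 139 ± 24.8. Cd4 was 5040 ± 42.7 with vehicle and 4230 ± 23.1 with antibiotics, a fall of 0.25 ± 0.05 in log2 (adjusted p = 0.0111) that lost its call without lymphoma antibiotic library 1 (adjusted p = 0.0841) or 2 (adjusted p = 0.0762).

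Of 13846 genes tested, 1434 were higher and 1143 lower with antibiotics, 448 and 158 of them by at least 2-fold. The counts were 807 and 611 without lymphoma antibiotic library 1, 754 and 564 without antibiotic library 2, and 2293 and 1798 without vehicle library 2. With TMM scaling, which moved the median of all genes from 0.007 to 0.058 in log2, they were 2001 and 802. Tet2 stood at 361.6 and 376.2 with vehicle and 384.2 and 373.7 with antibiotics (log2 change 0.04, adjusted p = 0.680).

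With antibiotics, the largest rises in lymphoma included those of Slc4a1, Cd59a, Trnp1, Rhd, Tmcc2, Epb4.2, Cldn13, Ank1 and Alas2, most of them genes of the red cell membrane or of haem synthesis. Slc4a1 (chromosome 11, 102348820 to 102365281, protein coding) rose by 5.21 ± 0.16 in log2 (adjusted p = 3.04e-07). The largest falls there were those of Grb10, Gabra4, Art2b, Tnfsf4, Mcpt8, Dkk2, Asb4, Mirg, Prss34 and Apba2. Grb10 (chromosome 11, 11930499 to 12037428, protein coding) fell by 3.96 ± 0.22 in log2 (adjusted p = 1.22e-05). The basophil protease genes Mcpt8 and Prss34 fell from 214 ± 36.3 to 28.7 ± 6.73 and from 453 ± 78.8 to 81.6 ± 0.246. Their list of mast cell, basophil and eosinophil genes did not pass, with 4 of 12 lower and 2 higher (5 and 2 adjusted over the list alone, median -0.51, adjusted p = 0.246), and its member Cpa3 rose from 266 ± 5.71 to 378 ± 35.4. Tnfsf4, the ligand of the costimulator OX40, fell from 166 ± 36.9 to 18.9 ± 8.16. Without lymphoma antibiotic library 1, Art2b, Dkk2, Apba2 and Mirg lost their calls, with log2 changes of -3.05, -2.67, -1.97 and -2.21. Without antibiotic library 2, Art2b, Dkk2 and Apba2 did so, with log2 changes of -3.22, -2.69 and -2.15. These genes kept their calls with a spread from the lymphoma libraries alone, with edgeR and with DESeq2.

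Of the 43 lists, 15 passed in camera for antibiotics in lymphoma, and 4 of them also with an estimated correlation, each at adjusted p = 0.0191. The first was the erythroid list, with all 17 tested members of 23 higher and a median of 3.35 (adjusted p = 2.3e-22), led by the carbonic anhydrase gene Car2, which rose from 192 ± 15.1 to 1980 ± 15.9. Of its 6 globin genes, 5 were too low to be tested. The next was the macrophage list, with 16 of 17 higher (17 adjusted over the list alone) and a median of 1.68 (adjusted p = 2.38e-20). Besides Vcam1 (chromosome 3, 116110020 to 116129688, protein coding; log2 change 2.64 ± 0.06, adjusted p = 3.96e-08), the lipoprotein gene Apoe rose from 295 ± 23.3 to 974 ± 50.7 and the complement gene C1qb from 113 ± 2.45 to 379 ± 33. The third was MHC class I, with 11 of 13 genes lower (12 adjusted over the list alone) and a median of -0.45 (adjusted p = 4.01e-14). H2-K1 (chromosome 17, 33996012 to 34000619, protein coding) fell by 0.86 ± 0.02 in log2 (adjusted p = 3.96e-08), and Nlrc5, the activator of MHC class I genes, fell from 613 ± 1.36 to 339 ± 5.45. The fourth was the interferon gamma response, with 16 of 26 lower (17 adjusted over the list alone) and a median of -0.36 (adjusted p = 3.16e-10), including Irf1, from 1390 ± 49.9 to 1020 ± 21.4.

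The other 11 lists passed in camera only with the preset correlation. Neutrophil genes had a median of -0.36, with 10 of 21 lower and 2 higher (11 and 3 adjusted over the list alone, adjusted p = 0.000126, and 0.0785 with an estimated correlation). Primary granule genes had a median of -0.52, with 5 of 8 lower (adjusted p = 0.000126, and 0.0785 with an estimated correlation), Mpo falling from 1030 ± 44 to 654 ± 9.02. The TNF and NF-kB list had a median of -0.07, with 7 of 26 lower and 2 higher (adjusted p = 0.011, and 0.124 with an estimated correlation), Nfkb2 falling from 511 ± 7.64 to 331 ± 0.703. It lost its call without lymphoma vehicle library 2 (adjusted p = 0.16). IL-6, JAK and STAT3 genes had a median of -0.16, with 8 of 20 lower and 2 higher (10 and 2 adjusted over the list alone, adjusted p = 0.00313, and 0.115 with an estimated correlation), Cish falling from 282 ± 30.1 to 115 ± 2.43. The TNF superfamily had a median of -0.38, with 5 of 22 lower (adjusted p = 0.00407, 0.115 with an estimated correlation, and 0.0716 at a mean of at least 50). The unfolded protein and stress response had a median of -0.12, with 6 of 20 lower and 1 higher (adjusted p = 0.00206, and 0.132 with an estimated correlation).

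Type I interferon genes had a median of -0.28, with 7 of 32 lower and 2 higher (12 and 4 adjusted over the list alone, adjusted p = 0.00971, and 0.119 with an estimated correlation). Rsad2, an antiviral gene of that list, moved against it, from 92.6 ± 21 to 321 ± 15.2. The list lost its call without lymphoma vehicle library 1 (adjusted p = 0.0657). Follicular helper genes had a median of -0.35, with 5 of 17 lower and 1 higher (6 and 1 adjusted over the list alone, adjusted p = 0.0326, and 0.17 with an estimated correlation). They lost the call with 1 of the 4 libraries left out, with adjusted p of 0.0514 and 0.0806 without antibiotic library 1 and 2, 0.0555 and 0.211 without vehicle library 1 and 2, and also at a mean of at least 50 (0.0871). The transcription factor gene Batf of that list fell from 266 ± 0.139 to 179 ± 5.46. Oxidative phosphorylation had a median of -0.06, with 7 of 49 lower and 1 higher (adjusted p = 0.0199, and 0.423 with an estimated correlation). It lost its call with TMM scaling (0.0665), without antibiotic library 2 (0.0655) and without vehicle library 2 (0.271).

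Monocyte genes had a median of 0.21, with 9 of 19 higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.0256, and 0.247 with an estimated correlation), Csf1r rising from 165 ± 18.7 to 340 ± 0.239. They lost the call with TMM scaling (0.0559) and without lymphoma antibiotic library 2 (0.185). G2/M genes had a median of 0.09, with 9 of 34 higher (11 higher and 3 lower adjusted over the list alone, adjusted p = 0.0442, and 0.17 with an estimated correlation), Mki67 rising from 7090 ± 12.1 to 8910 ± 102. They lost the call at a mean of at least 50 (0.0529), without antibiotic library 1 (0.0745) or 2 (0.0684) and without vehicle library 2 (0.222). B cell genes did not pass (median 0.01, adjusted p = 0.733).

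The genes that most separated lymphoma from normal CD4+ T cells were followed in the treated lymphoma. Of the 200 genes lowest in lymphoma 171 were tested with antibiotics, and 56 rose and 5 fell, with a median of 0.635 (camera adjusted p = 4.5e-06, and 0.00299 with an estimated correlation). With a pseudocount of 5 the median of these genes was only 0.255, with 48 higher and 6 lower (camera adjusted p = 1.35e-05). Of the 200 highest in lymphoma 182 were tested, 18 rose and 27 fell, with a median of -0.031 (adjusted p = 0.23). After the data were seen, the test was repeated without the members of lists of other cell types, which were only 16 of the 200 lowest genes and 4 of the 200 highest. The medians were then 0.486 (adjusted p = 0.000182) and -0.02 (adjusted p = 0.295). Across 13187 genes, the log2 changes of both comparisons had a Pearson r of -0.18 and a Spearman rho of -0.05, and genes are not independent replicates.

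**Figure D3:**
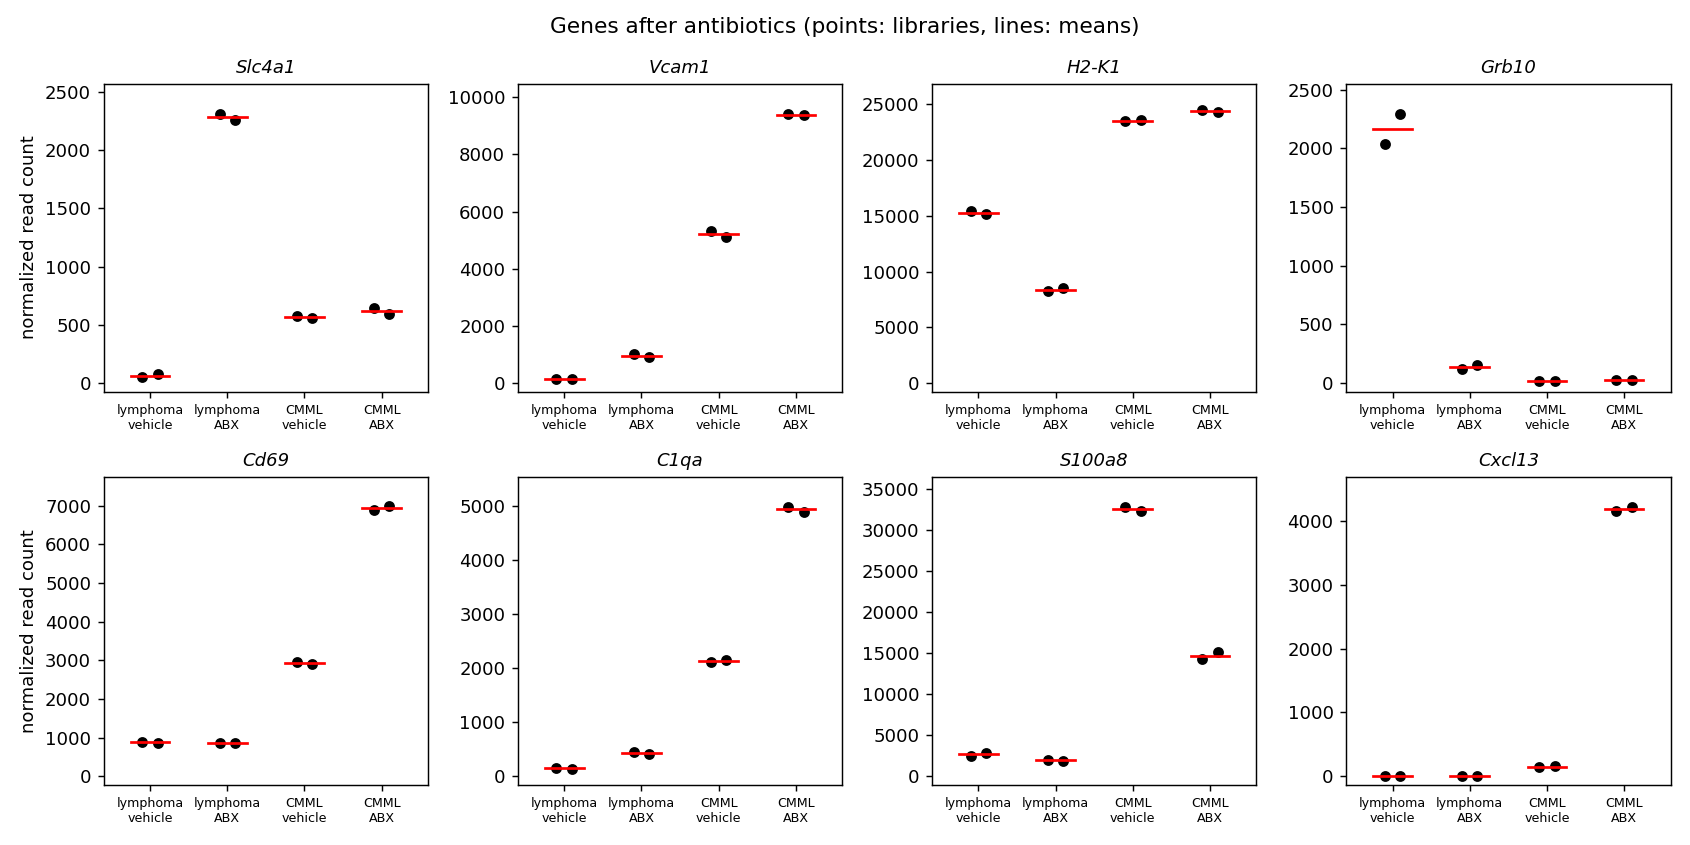
Normalized read counts (linear axes) of Slc4a1, Vcam1, H2-K1, Grb10, Cd69, C1qa, S100a8 and Cxcl13 in each library of lymphoma and CMML with vehicle and with antibiotics, with group means. Lymphoma and CMML values are on separate scales, so only groups of the same disease can be compared, as for Slc4a1, which was 62.1 and 2280 in lymphoma.

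The comparison of antibiotics with vehicle in CMML asked the same question in the myeloid disease. Samples from treated mice held more transcripts of immediate early genes, which cells switch on within minutes of a stimulus: Cd69 rose from 2930 ± 37.6 to 6940 ± 86.6. The complement gene C1qa, made by macrophages, rose from 2130 ± 22.5 to 4940 ± 61.7. Neutrophil genes fell, S100a8 from 32600 ± 374 to 14700 ± 669 and Mpo from 44100 ± 12.2 to 22800 ± 391. The chemokine gene Cxcl13, which draws B cells into follicles, rose from 149 ± 10.3 to 4190 ± 37.6. Mecom, a transcription factor of blood stem cells, fell from 119 ± 1.04 to 1.97 ± 0.059.

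Of 13846 genes tested, 1142 were higher and 1518 lower with antibiotics in CMML, 175 and 180 of them by at least 2-fold. The counts were 506 and 774 without CMML antibiotic library 1, and 515 and 801 without antibiotic library 2. They were 545 and 694 without CMML vehicle library 1, and 563 and 732 without vehicle library 2. With a spread from the CMML libraries alone they were 2954 and 3045. Tet2 stood at 1806 and 1753 with vehicle and 1588 and 1673 with antibiotics (log2 change -0.13, adjusted p = 0.155).

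In CMML the largest rises included those of Cxcl13, Htra1, Serpina3h, Rnf217, Pmp22, Scel, Dhrs9, Ifi205 and Retnla. Cxcl13 (chromosome 5, 95956939 to 95961068, protein coding) rose by 4.8 ± 0.44 in log2 (adjusted p = 0.000142), and Retnla, a gene of alternatively activated macrophages, from 25.3 ± 2.13 to 102 ± 1.83. The largest falls in CMML were those of Mecom, Serpinb9e, Serpinb9g, Nnmt, Aldh1a1, Aldh1a7, Slpi, Agpat9, Il5ra and Olfm4. Mecom (chromosome 3, 29951296 to 30509759, protein coding) fell by 5.34 ± 0.46 in log2 (adjusted p = 0.0001), Aldh1a1, a retinoic acid synthesis gene, from 513 ± 13.4 to 78.8 ± 0.428, and the protease inhibitor gene Slpi from 3600 ± 40.9 to 699 ± 4.15. Htra1, Rnf217, Pmp22, Dhrs9, Ifi205 and Olfm4 lost their calls without any 1 of the 4 CMML libraries, with adjusted p from 0.0682 (Htra1 without vehicle library 2) to 0.207 (Olfm4 without vehicle library 2). With all libraries kept, Pmp22, Dhrs9 and Olfm4 also lost their calls with a pseudocount of 0.5 (0.119, 0.0892 and 0.0644), with no filter (0.0674, 0.0518 and 0.0636) and with TMM scaling (0.0777, 0.0615 and 0.0515). Rnf217 did so with a pseudocount of 0.5 (0.0656) and Ifi205 with no filter (0.0519). With a spread from the CMML libraries alone, with edgeR and with DESeq2, Htra1, Rnf217, Pmp22, Dhrs9, Ifi205 and Olfm4 all kept their calls. Serpina3h lost its call without antibiotic library 1 (0.0662) or vehicle library 1 (0.0563), and Scel without antibiotic library 1 (0.0698) or 2 (0.0584) or vehicle library 2 (0.0698).

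Of the 43 lists, 22 passed in camera for antibiotics in CMML, and 10 of them with an estimated correlation. Immediate early genes led, with 18 of 21 higher (19 adjusted over the list alone) and a median of 0.64 (adjusted p = 1.64e-19, and 0.0157 with an estimated correlation). Cd69 (chromosome 6, 129267324 to 129275375, protein coding) rose by 1.24 ± 0.03 in log2 (adjusted p = 2.33e-07), and the phosphatase gene Dusp1 from 5290 ± 23.3 to 8880 ± 3.17. The TNF and NF-kB list rose with it, 11 of 26 genes higher and 2 lower with a median of 0.27 (adjusted p = 0.000264, and 0.0499 with an estimated correlation), and its feedback inhibitor Tnfaip3 went from 1320 ± 42.2 to 2970 ± 102. Macrophage genes had a median of 0.87, with 13 of 17 higher (15 adjusted over the list alone, adjusted p = 5.5e-13, and 0.0157 with an estimated correlation). Type I interferon genes had a median of 0.34, with 9 of 32 higher (12 adjusted over the list alone, adjusted p = 3.81e-07, and 0.0247 with an estimated correlation), Irf7 rising from 799 ± 32.5 to 1310 ± 19.8.

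Neutrophil genes had a median of -0.86 in CMML with antibiotics, with 15 of 21 lower (16 lower and 1 higher adjusted over the list alone, adjusted p = 2.4e-11, and 0.0157 with an estimated correlation). Primary granule genes had a median of -1.07, with 7 of 8 lower and 1 higher (adjusted p = 1.12e-06, and 0.0277 with an estimated correlation). Mpo (chromosome 11, 87793784 to 87804412, protein coding) fell by 0.95 ± 0.03 in log2 (adjusted p = 8.5e-07), and Gfi1, a transcription factor that neutrophil precursors need, fell from 808 ± 7.49 to 319 ± 6.05. Growth lists fell by small amounts. MYC and ribosome biogenesis had a median of -0.19, with 21 of 30 lower (24 adjusted over the list alone, adjusted p = 2.4e-11, and 0.0157 with an estimated correlation). G1/S genes had a median of -0.2, with 18 of 34 lower (21 adjusted over the list alone, adjusted p = 1.33e-09, and 0.0157 with an estimated correlation), E2f2 falling from 2900 ± 112 to 1540 ± 27.1. G2/M genes had a median of -0.19, with 18 of 34 lower and 1 higher (20 and 2 adjusted over the list alone, adjusted p = 9.32e-06, and 0.0277 with an estimated correlation). Glycolysis and hypoxia genes had a median of -0.22, with 11 of 24 lower and 1 higher (16 and 2 adjusted over the list alone, adjusted p = 4.52e-06, and 0.0277 with an estimated correlation), Pkm falling from 25100 ± 308 to 18200 ± 28.8.

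The other 12 lists passed in camera only with the preset correlation. Ribosomal proteins had a median of -0.2, with 25 of 45 lower (26 adjusted over the list alone, adjusted p = 2.4e-11, and 0.121 with an estimated correlation). Oxidative phosphorylation had a median of -0.17, with 17 of 49 lower and 1 higher (20 and 2 adjusted over the list alone, adjusted p = 3.45e-06, and 0.121 with an estimated correlation). B cell genes had a median of -1.22, with 9 of 16 lower (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.000162, and 0.115 with an estimated correlation). The myeloid identity list had a median of -0.24, with 8 of 20 lower and 1 higher (11 and 3 adjusted over the list alone, adjusted p = 0.0122, and 0.115 with an estimated correlation). Interferon gamma genes had a median of 0.27, with 9 of 26 higher and 3 lower (11 and 5 adjusted over the list alone, adjusted p = 0.0127, 0.115 with an estimated correlation, and 0.0542 without CMML antibiotic library 1). The inflammatory cytokine list had a median of 0.46, with 3 of 26 higher (adjusted p = 0.0122, 0.115 with an estimated correlation, and 0.057 at a mean of at least 50).

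Dendritic cell genes had a median of 0.76, with 3 of 12 higher (6 adjusted over the list alone, adjusted p = 0.00903, and 0.121 with an estimated correlation). Th1 and cytotoxic genes had a median of 0.64, with 5 of 15 higher (6 adjusted over the list alone, adjusted p = 0.00878, and 0.13 with an estimated correlation), Gzma rising from 26 ± 12.2 to 74.8 ± 1.94. CD8 and NK cell genes had a median of 0.94, with 3 of 10 higher (4 adjusted over the list alone, adjusted p = 0.0122, and 0.121 with an estimated correlation), and too few had a mean of at least 50 to be tested there. Th2 genes had a median of 0.77, with 3 of 8 higher (adjusted p = 0.0189, 0.136 with an estimated correlation, and 0.085 without CMML antibiotic library 1). Erythroid genes had a median of 0.28, with 2 of 17 higher (adjusted p = 0.0198, and 0.266 with an estimated correlation), and lost the call without antibiotic library 2 (0.0725) or vehicle library 2 (0.122). Naive T cell genes had a median of 0.46, with 4 of 11 higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.0461, and 0.36 with an estimated correlation). They lost the call with a pseudocount of 5 (0.0568), with TMM scaling (0.0511) and without antibiotic library 1 (0.146). The monocyte list did not pass (median 0.3, adjusted p = 0.165): Ly6c2, a gene of classical monocytes, fell from 13600 ± 71 to 5020 ± 17.1, while Cx3cr1, a gene of patrolling monocytes, rose from 675 ± 10.5 to 1270 ± 16.9.

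**Figure D4:**
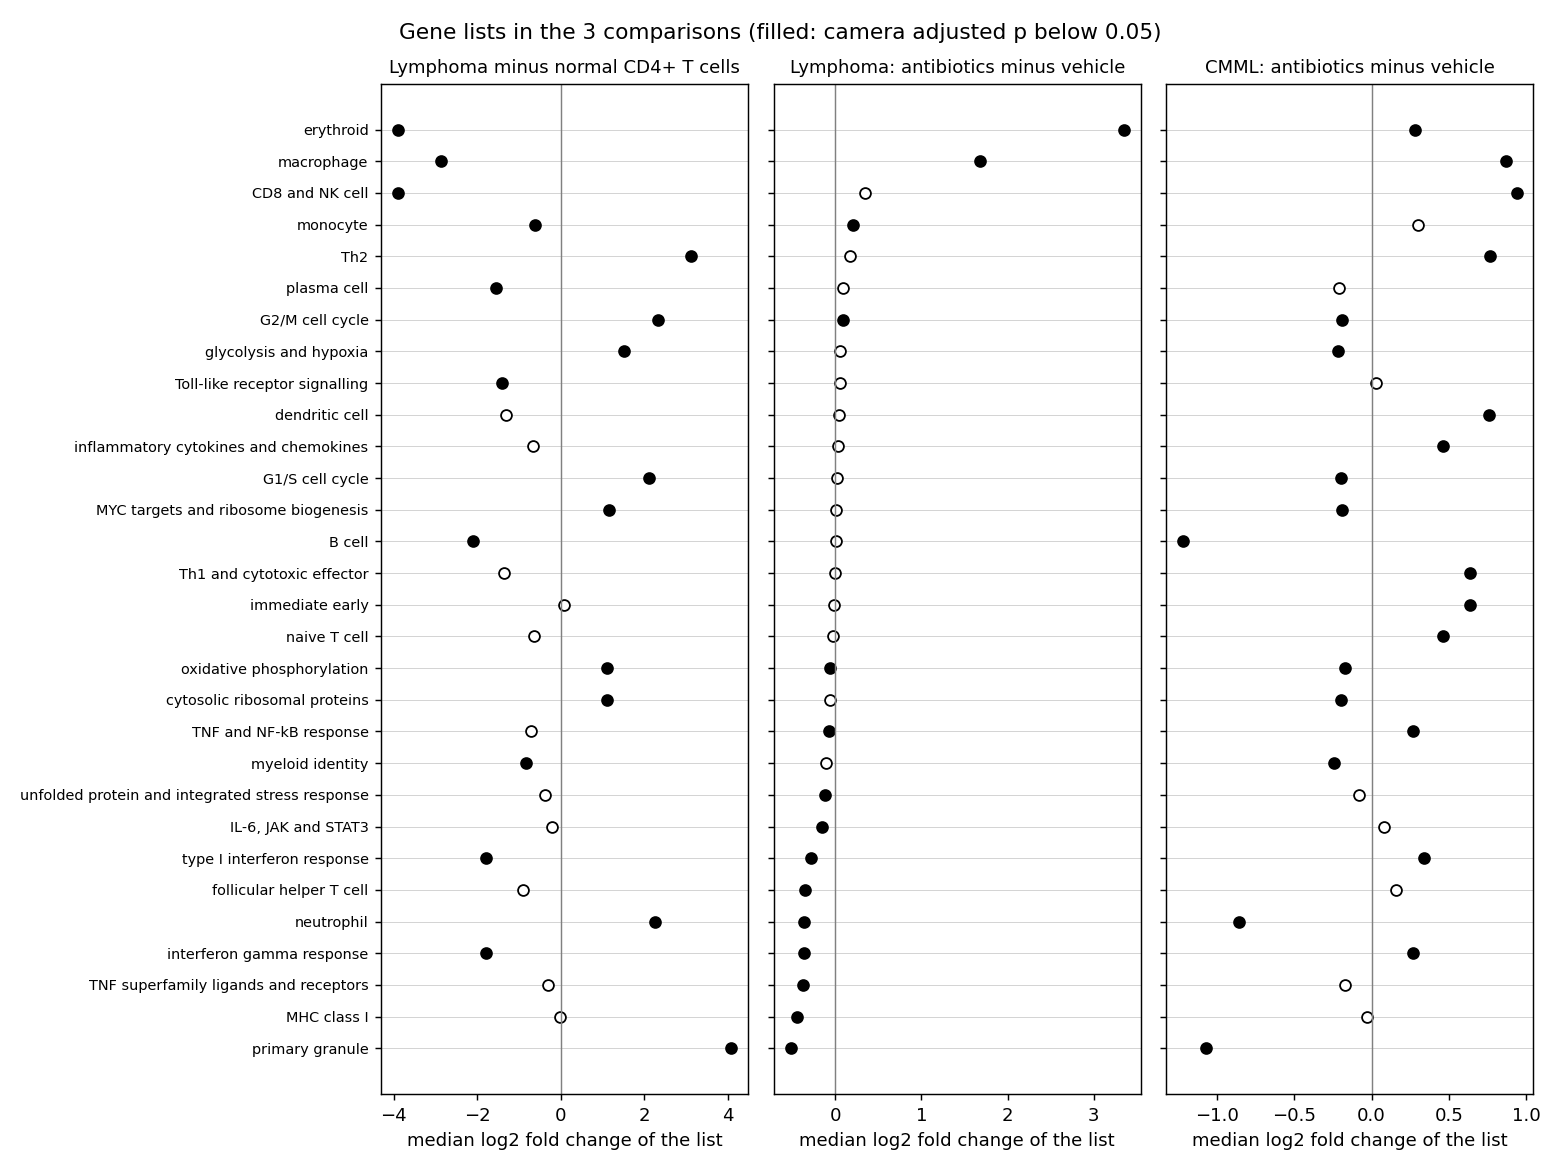
Median log2 fold change of each gene list that passed camera in at least 1 of 3 comparisons, lymphoma against normal CD4+ T cells and antibiotics against vehicle in lymphoma and in CMML, with filled points for lists past the threshold. The x axes differ between the 3 panels, and erythroid genes reach 3.35 in lymphoma with antibiotics and 0.28 in CMML.

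The antibiotic effects in lymphoma and in CMML were compared by an interaction term. The immediate early gene Cd69 rose in CMML and was 877 and 870 with vehicle and antibiotics in lymphoma, with a difference of -1.25 ± 0.05 in log2 between the effects (adjusted p = 1.7e-06). The red cell gene Slc4a1 rose in lymphoma and was 571 and 617 in CMML, with a difference of 5.09 ± 0.22 (adjusted p = 4.11e-06). Across genes, 1578 effects were higher and 1097 lower in lymphoma than in CMML, 384 and 239 of them by at least 2-fold. The counts were 2544 and 1821 without lymphoma vehicle library 2, 1035 higher without lymphoma antibiotic library 1 and 1045 higher without antibiotic library 2, and 1966 and 881 with TMM scaling. They were 890 and 600 without CMML antibiotic library 1, 881 and 571 without antibiotic library 2, 812 and 607 without CMML vehicle library 1, and 829 and 605 without vehicle library 2.

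Of the genes with a changed level in both diseases, 238 rose in both, where 118 would be if the calls were independent, and 231 fell in both, where 125 would be. Opposite directions were also shared by more genes than that: 222 rose in lymphoma and fell in CMML (157 if independent), and 185 fell in lymphoma and rose in CMML (94.3 if independent). Both comparisons used the same estimate of the spread for each gene, so a gene with a low estimate passes more readily in both. Independent calls were therefore not to be awaited, and the excess is no evidence of a shared response. Across 13846 genes the log2 effects had a Pearson r of 0.09 and a Spearman rho of 0.06, and genes are not independent replicates.

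CMML vehicle against lymphoma vehicle served as a check of cell identity. The neutrophil and monocyte genes Mpo and Lyz2 were 44100 ± 12.2 and 33000 ± 36.5 in CMML, and 1030 ± 44 and 1000 ± 10.2 in lymphoma. Cd4 and Cd3e were 119 ± 3.92 and 8.49 ± 0.943 in CMML, and 5040 ± 42.7 and 3270 ± 43.8 in lymphoma. CMML samples also held the platelet integrin gene Itga2b at 34900 ± 654, against 25.9 ± 7.26. These 5 genes were chosen as markers after their values were seen. As the diseases were scaled apart, the median of all genes was 1.185 in log2 as deposited and 0.102 with TMM scaling, so the 10707 genes higher and 1655 lower in CMML cannot be read as a balance, and with TMM scaling they were 5864 and 5054. The largest differences as deposited were those of Slc35d3, Mmrn1, Kdr, Pde5a and Rab27b, higher in CMML, and Folr4, Sh2d1a, Map2, Stc2 and Fam84a, lower. Kdr, a receptor of vascular growth factor, had 0 reads in lymphoma, and Stc2 and Fam84a had 0 in CMML, and no folds are given across the separate scales. Sh2d1a, a T cell signalling adaptor, was 1.83 ± 2.59 in CMML and 2670 ± 90.7 in lymphoma.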

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

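The results of this part are differences between the antibiotic effect in lymphoma and that in CMML that passed the interaction test, in limma for genes and in camera for lists. The tests of single animals, of globin genes, of the neutrophil share as the cause of the whole pattern and of handling were chosen after the results were seen.

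Antibiotic effects were higher in lymphoma than in CMML for 1578 genes and lower for 1097. The largest positive differences in log2 included those of Aldh1a1 (5.46), Slc4a1 (5.09), Serpinb9e (4.88) and Mecom (4.82). Aldh1a1 was 9.84 with vehicle and 62.1 with antibiotics in lymphoma, and 513 and 78.8 in CMML. The largest negative ones were those of Cxcl13 (-6.13), Grb10 (-4.58), H2-M2 (-3.97), Gabra4 (-3.74) and Parm1 (-3.37). Parm1 had 23 reads in lymphoma with vehicle and 3 with antibiotics, lower by a ratio of 15.6 (counting interval 4.7 to 81). Grb10 fell from 2170 to 139 in lymphoma and was 16.9 and 26.5 in CMML, and H2-M2, a class I-like gene, was 86.9 and 28.3 in lymphoma and 7.78 and 44.1 in CMML. Serpinb9e and Mecom had at most 1 read in the lymphoma libraries, Cxcl13 4 in all, and Gabra4 0 in the CMML libraries, so their differences describe 1 disease and depend on the pseudocount. With edgeR, Serpinb9e, Mecom and Gabra4 did not pass (adjusted p of 1, 0.917 and 1), nor with DESeq2 (0.211, 0.306 and 0.225).

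Of the 43 lists, 18 passed. Effects were higher in lymphoma for erythroid genes (median difference 2.92), B cell genes (1.01), macrophage genes (0.76), primary granule genes (0.6), neutrophil genes (0.52), G1/S genes (0.26), MYC and ribosome biogenesis (0.23), G2/M genes (0.22), glycolysis and hypoxia (0.22) and ribosomal proteins (0.14). They were lower in lymphoma for dendritic cell genes (-1.01), the interferon gamma response (-0.75), the type I interferon response (-0.57), immediate early genes (-0.55), follicular helper genes (-0.53), the TNF and NF-kB response (-0.45), MHC class I (-0.38) and IL-6, JAK and STAT3 genes (-0.23). With an estimated correlation 11 of the 18 passed. The other 7 did not: B cell genes (adjusted p = 0.147), primary granule genes (0.111), neutrophil genes (0.103), ribosomal proteins (0.315), dendritic cell genes (0.203), follicular helper genes (0.147) and IL-6, JAK and STAT3 genes (0.0929).

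In lymphoma with antibiotics, genes of red cell precursors and of the macrophages of spleen and marrow rose together, as Slc4a1 and Vcam1 show. With all 4 libraries thinned to 4364587 reads, the erythroid median was 3.27 against 3.35, and the macrophage median 1.73 against 1.68. Thinned reads were scaled back, which leaves the expected normalized values unchanged. The test therefore argues only against low counts and the pseudocount at unequal depth, and says nothing else about depth. Red cell precursors in the treated samples may account for the erythroid part: a second list of 24 erythroid genes, none in the first and 23 tested, had 18 genes higher and a median of 1.24 (quartiles 0.55 and 1.75). Globin genes do not decide it: Hbb-bs had 34 reads beside 6717 of Slc4a1 there, but also only 29 beside 7091 in normal CD4+ T cells, and the macrophage genes are not accounted for by red cell precursors alone. A difference between single mice cannot be told apart from an effect of the antibiotics, which stays open too, since no replicate pair of these groups exceeded a chi-square per degree of freedom of 2.37 and the labels do not tie libraries to animals.

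In CMML with antibiotics, immediate early and macrophage genes rose and neutrophil genes fell. A lower share of neutrophils as the whole cause would raise the genes of other cells alike. The medians of macrophage and B cell genes lay 2.09 apart, and their means 1.65. The SE of 0.23 for the means was taken over genes as if they were independent, which they are not. The B cell list did not pass camera with an estimated correlation (adjusted p = 0.115). The gap therefore argues only weakly against a lower share of neutrophils as the whole cause. A lower share of neutrophils and their precursors may account for the neutrophil genes, as a second list of 20 such genes, none in the first, had 11 lower, 0 higher and a median of -0.62 (quartiles -1.19 and -0.07). Handling of the cells before lysis, which also induces immediate early genes, stays open: heat shock genes had a median of 0.04, with 3 of 12 higher and 4 lower and a test pointing down (adjusted p = 0.355). A difference between single mice cannot be told apart from an effect of the antibiotics here either. The chi-square per degree of freedom was 1.5 for CMML vehicle and 1.51 for CMML with antibiotics. The labels do not tie these libraries to animals. A change within the leukaemic cells after antibiotics, the biological reading that the design offers, was not tested apart from these.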

How the results depend on the processing

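Of the values of named genes under other settings, 4290 kept their direction and side of the threshold, 131 fell below it, 8 passed it and 2 turned. Genes named by the rule were chosen from these same data for large changes or small p. Those without overlap between groups could not turn when a library was left out, so these counts say little about robustness. Both turns were of Cd4 in lymphoma against normal cells, at 0.15 without lymphoma library 1 and 0.05 without normal CD4+ library 1, in a range of -0.22 to 0.15, and it passed in neither. Counts of genes moved more. With each library left out in turn, they ran from 1768 to 4754 higher and 1277 to 5702 lower for lymphoma against normal cells, with 5702 without lymphoma library 1. They ran from 754 to 2293 and 564 to 1798 for antibiotics in lymphoma, from 506 to 563 and 694 to 801 in CMML, and from 812 to 2544 and 571 to 1821 for the interaction. A minimum 2-fold change, fewer genes by construction, left 448 and 158 in lymphoma, 175 and 180 in CMML and 384 and 239 for the interaction. A spread from the compared groups alone gave 897 higher in lymphoma and 2954 and 3045 in CMML, and edgeR gave 2450 and 2499 in CMML. The log2 difference between the 2 libraries of a group, over genes with a mean of at least 50, varied more in lymphoma. Its SD was 0.238 for lymphoma vehicle, 0.146 for lymphoma with antibiotics and 0.131 for both CMML groups. A spread shared by all groups is thus wider than that of CMML and narrower than that of lymphoma. This bears on the fits of the compared groups alone. Leaving out a library also takes its pair out of the shared spread. For lymphoma against normal cells and for antibiotics in lymphoma, both libraries of a pair moved the counts in the same direction. Beyond that, the cause was not tested for these counts, for the left-out libraries or for Cd4. TMM scaling shifted the split to 2001 and 802 in lymphoma and to 1966 and 881 for the interaction. For CMML against lymphoma it gave 5864 and 5054, quantile normalization 5055 and 5857, edgeR 5668 and 5427 and DESeq2 5516 and 4959, because each rescales diseases that were deposited on separate scales. Lists past the threshold were 0, 4 and 10 with an estimated correlation and 34, 28 and 37 with fry, against 19, 15 and 22 with camera for lymphoma, antibiotics in lymphoma and antibiotics in CMML, and 18 to 21, 11 to 15 and 20 to 22 with a library left out. The genes highest in lymphoma had a median of -0.031 with antibiotics that passed in fry (adjusted p = 0.00458), 0.02 with TMM scaling, where camera pointed down (adjusted p = 0.0341), and -0.019 to 0.043 with a library left out. Those lowest in lymphoma had 0.538 to 0.752 with a library left out, 0.255 with a pseudocount of 5 and 0.783 with TMM scaling. A fit of the compared groups alone does not apply to the interaction, which uses all 4. Depth limits lymphoma library 2 most, where 2916648 reads put 1 read at 7.297 on the normalized scale.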

Other observations

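Among the genes higher in the lymphoma than in normal CD4+ T cells were 5 imprinted genes, which are expressed from 1 parental copy: Dlk1, Grb10, Asb4, H19 and Mirg. They were chosen after their values were seen, and no list of imprinted genes was tested, so they do not stand for imprinted genes in general. Grb10 rose from 37.1 ± 8.65 in normal CD4+ T cells to 3810 ± 586 in lymphoma (adjusted p = 0.000447), Asb4 from 3.38 ± 2.68 to 340 ± 171 (adjusted p = 0.00127), and the non-coding RNA H19 was at least 181-fold higher. Mirg, a non-coding RNA from the same imprinted region as Dlk1, was higher by a ratio of 433, with a counting interval of 76.9 to 17200. All but Dlk1 were lower with antibiotics than with vehicle in the transferred lymphoma, where Grb10, Asb4 and Mirg were also picked for their large falls: Grb10 fell from 2170 ± 180 to 139 ± 24.8, Asb4 from 146 ± 12.1 to 22.5 ± 3.05 and H19 from 28.5 ± 16.9 to 1.36 ± 0.0683 (adjusted p = 0.00191). Mirg fell from 95.2 ± 2.72 to 16.4 ± 4.67, with an adjusted p of 0.00627, and of 0.0502 without lymphoma antibiotic library 1. Dlk1 was higher, at 2510 ± 97 with vehicle and 3110 ± 81 with antibiotics, which did not pass in limma (adjusted p = 0.794) but did in edgeR (8.93e-07), DESeq2 (6.15e-06) and a fit of the lymphoma libraries alone (0.000299). The limma spread was shared with the CMML libraries, where Dlk1 was near the floor, at 0 and 5.03 with antibiotics. The adjusted p of 0.794 therefore says little about lymphoma.

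Some megakaryocyte and platelet transcripts were abundant in the CMML libraries, in cells enriched with antibodies against Mac1 and Gr1. These genes were also chosen after their values were seen. Itga2b, the platelet integrin, was 34900 ± 654 with vehicle and 41100 ± 506 with antibiotics. The platelet chemokine gene Pf4 was 1830 ± 9.35 and 1850 ± 26.7, and Mmrn1, which encodes a protein of platelet granules, was 7660 ± 82.5 and 6990 ± 40.1. Gata1, a transcription factor of megakaryocytes and red cells, was 3230 ± 42.9 and 3612 ± 80.6. None of these 4 passed the test of antibiotics in CMML, nor did the fixed megakaryocyte and platelet list, with 1 of 12 higher and 0 lower (adjusted p = 0.188, and 0.368 with an estimated correlation). The gene that rose was the integrin gene Itgb3, by 0.51 ± 0.03 in log2 (adjusted p = 1.35e-05). The test shared its spread with the lymphoma libraries, where Itga2b, Pf4 and Mmrn1 had few reads. Mmrn1, for example, had 2 reads there with vehicle and 7 with antibiotics. Not passing is therefore no evidence that the 4 genes kept their levels in CMML.

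Xist and Y-linked reads occurred together in the primary lymphoma libraries. Both tests of this pattern were chosen after the values were seen. Xist was 15020 and 6538 in lymphoma libraries 1 and 2 and 3.298 and 5.963 in those of normal CD4+ T cells, while Ddx3y stood at 27% and 8% of its mean in normal cells, Kdm5d at 12.7% and 6.04%, Uty at 13.9% and 8.72% and Eif2s3y at 32.8% and 19.1%. Misassigned reads are argued against, since the 4 Y-linked genes had at most 2 reads in any library of the antibiotic table, all rich in Xist. The lowest read count among Xist and the 4 genes in either lymphoma library was 13, which only restates the pattern and decides nothing about its cause. Cells of male and female mice in the same sample may account for the pattern. Whether such cells were pooled, or were carried over from another mouse, is not given in the labels, and no biological explanation was tested.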
